A study of Homo sapiens with 8 samples.

How the data were processed

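RNA-seq was done on total RNA of U2OS cells, an established human osteosarcoma cell line. Per the labels, 8 libraries fall into 4 groups of 2: cells with neither factor (WT), cells overexpressing MYC (MYC), cells with Zab (Zab), and cells with Zab and overexpressed MYC (Zab+MYC). Zab stands for Zαβ, which in general use is the pair of Z-nucleic-acid-binding domains of the RNA-editing enzyme ADAR1. The construct itself is described no further in the labels. RNA was extracted with Trizol and libraries were made with an Abclonal kit, per the labels' protocols. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

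The authors deposited 1 table per library, which gives an exon signal for each of 19414 genes, not whole counts. Per the submitters' processing notes, Trim Galore 0.6.6, STAR and HOMER 4.11.1 were used, and the builds hg19 and dm6 are listed with no role given. The STAR version is not given in the sources used here. Per the file headers, HOMER's analyzeRepeats program counted raw tags in the exons of hg19 RefSeq coding genes and kept 1 transcript per gene symbol. Each library's folder was named for a spike-in, per the file headers. In every library 100% of the values were whole multiples of 1 step, within a tolerance of 0.1 step, so the deposited signal is tags times 1 factor per library. A tag was taken as 2 steps, which is an assumption. With 1 step per tag all tag numbers would be larger by the same factor. Tags in exons would then exceed the tag total in the file header in every library, which argues against it. At 2 steps they made up 60.6% to 76.1% of that total. The scaling factor ran from 0.315 to 0.537 deposited units per tag. How it was set is not given in the sources used here, so the deposited scale is reported only as an alternative.

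The counting can affect some genes. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes are uncertain. Near-identical families are uncertain too, which includes ribosomal proteins, replication-dependent histones, HLA, IFITM, OAS and keratin paralogs. The transcript kept for a symbol differed between libraries for 50.6% of the genes, and 9594 genes had the same transcript in all 8 libraries. Introduced and endogenous MYC transcripts, and Zab and endogenous ADAR transcripts, are not separated in the values. Coordinates are hg19, 1-based, as the deposited tables give them. The reference genome at hand is of another build and was not used. Mitochondrially encoded genes were not analysed here.

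Tags were recovered by dividing each value by the worth of 1 tag in its library, that is 2 steps. Exon tags per library ran from 686992 to 1326170, which limits what can be seen for low genes. Counting intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. The other intervals, given with slopes, shares of genes and medians of list members, are over genes. They treat genes as independent and cover no spread between libraries. A floor is 3 counts over the group. Genes were kept with filterByExpr, which left 9673. Values were scaled to CPM, tags per library total, with TMM factors and taken to log2(CPM + 2). limma with a mean-variance trend was fitted to all 8 libraries with 1 mean per group and 4 residual degrees of freedom. The spread of each gene was moderated towards a trend over all genes. Very small p-values rest on that pooled spread and could not arise from 4 degrees of freedom alone. The common dispersion in edgeR, a measure of spread beyond counting noise, was 0.00017. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 called. Fold changes are on the log2(CPM + 2) scale, which understates the change of low genes. CPM values are given as mean ± SD over 2 libraries, and log2 fold changes as ± SE.

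Before the data were examined, the values had been assumed to be counts and edgeR's quasi-likelihood test had been planned. Because the deposited values are a scaled signal, limma took its place, and the edgeR test on recovered tags, rounded, was added as an alternative after seeing the data. The other added alternatives were pseudocounts of 1 and 5 CPM, the deposited scale, genes with the same transcript in all 8 libraries, gene lists without ADAR, and the WT libraries split between comparisons. Chosen beforehand were RLE scaling, library totals, no filter, a filter of 5 CPM in 2 libraries, DESeq2, the 4 libraries compared alone, replicate number as a block, an added 2-fold threshold, thinning to the smallest library, an estimated correlation for gene lists, and each library left out in turn. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

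The limma and edgeR steps were tested on simulated data drawn for MYC against WT. Among 9423 genes tested there, limma called 60% of genes changed 2-fold, 27% of genes changed 1.5-fold and 1 unchanged gene. edgeR called 66%, 35% and 5 unchanged genes. The slope of fitted on true log2 fold for limma was 0.937. Only a small part of the genes was changed there, as often up as down, with a dispersion set above the 0.00017 that edgeR gave. In the data limma called 58.2% of genes in MYC against WT. The simulation therefore does not check scaling or false calls where most genes move.

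Gene lists were fixed before the data were examined, 29 in all, of which 26 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The blood and neural marker lists had 2 and 4 tested members and are given as summed CPM. Named genes followed a rule fixed at the same time. It takes MYC, ADAR, SUPT16H and SSRP1 always. It adds, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall among those with at least 5 CPM in the higher group and ranges that do not overlap (6 and 6 for the interaction, without the range condition), with LOC, LINC, MIR and SNOR symbols counted but not named. Where no gene passes in a direction, the 3 with the smallest unadjusted p are given as values. For a described list it takes 2 to 4 tested members with the smallest p. Some genes that the rule takes are not reported here.

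Replicates were compared before averaging. The chi-square of tags per degree of freedom was 1.025 in WT, 1.00 in MYC, 1.005 in Zab and 0.997 in Zab+MYC. The unweighted chi-square p was 0.045, 0.495, 0.373 and 0.585. Weighted for tags counted as 1 step, which lower the noise, the value was 1.099, 1.081, 1.081 and 1.113. With that weight it lay above sampling noise in each group. The weight came only from values of 1 or 2 steps and was applied to all genes, so this excess depends on it. Over genes with more than 1000 tags the unweighted value was 1.23, 1.05, 1.27 and 1.43. No pair of files was identical, and each group has only 1 pair, so the libraries were kept as 2 per group. With 2 against 2 libraries an exact permutation test cannot give a p below 0.333.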

Results

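Gene expression was measured by RNA-seq in U2OS osteosarcoma cells with and without overexpressed MYC and with and without Zab. The series title links MYC, the histone chaperone FACT and Z-DNA, the left-handed form of DNA, and the design asks how MYC changes transcription when Zab, named for Z-nucleic-acid-binding domains, is present. Exon tags were 756377 and 909601 in the WT libraries, 1119460 and 1326170 in MYC, 686992 and 805346 in Zab, and 1037220 and 711206 in Zab+MYC. The share of tags that fell in exons of coding genes was 70.9% ± 0.342 (SD, n = 2) in WT, 76.0% ± 0.119 in MYC, 60.8% ± 0.192 in Zab and 69.1% ± 0.129 in Zab+MYC. The sum of deposited values was 407241 ± 1159 in WT, 428236 ± 1840 in MYC, 286967 ± 1431 in Zab and 327540 ± 802 in Zab+MYC, so that Zab lay at 0.705 of WT and Zab+MYC at 0.765 of MYC. The ranges of these groups do not overlap in exon share or sum. An exact permutation test of 2 against 2 gave its smallest p, 0.333, for each pair. Changes below are relative to TMM scaling. The deposited scale shifts all log2 fold changes by a median of -0.055 in MYC against WT, -0.516 in Zab against WT, -0.314 in Zab+MYC against MYC and 0.150 in Zab+MYC against Zab.

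**Figure D1:**
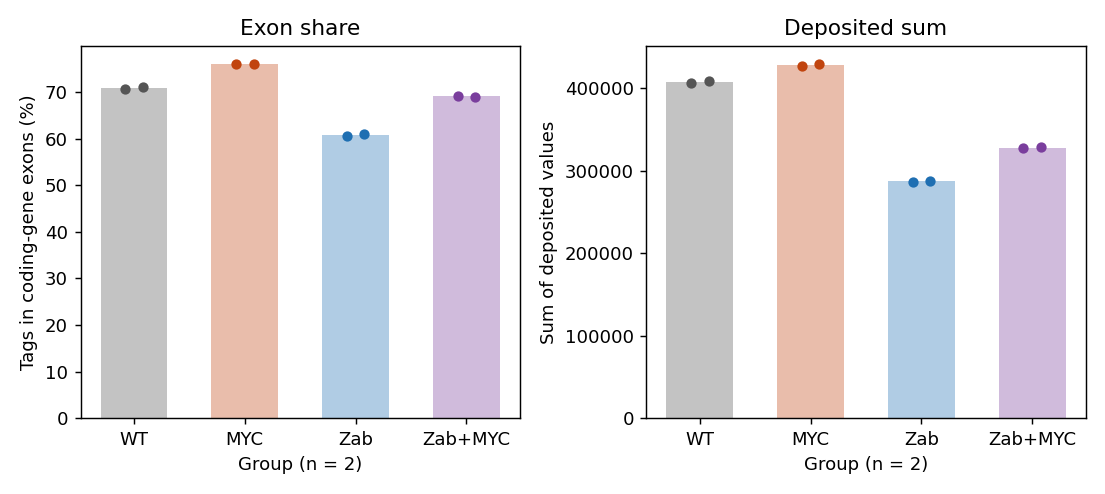
Percent of tags in coding-gene exons (left panel) and the sum of deposited values (right panel) by group, with bars for means and points for the 2 libraries of each group. Zab is lowest in both, at 60.8% and 286967.

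MYC was highest in the 2 groups labelled for it, and ADAR in the 2 groups labelled Zab. MYC, at chromosome 8 from 128748477 to 128755197 (hg19), stood at 83.7 ± 15.8 CPM (SD, n = 2) in WT, 1263 ± 37.1 in MYC, 212 ± 25.1 in Zab and 706 ± 1.27 in Zab+MYC. ADAR, the adenosine deaminase that edits double-stranded RNA, at chromosome 1 from 154554534 to 154578729, stood at 267 ± 3.75 CPM in WT, 239 ± 11.8 in MYC, 6100 ± 138 in Zab and 1043 ± 34.7 in Zab+MYC. MYC was 14.9-fold higher in MYC than in WT (log2 3.90 ± 0.091 SE, limma adjusted p = 3.5e-49) and 2.51-fold higher in Zab than in WT (log2 1.33 ± 0.091, limma adjusted p = 1.4e-20). It was 1.79-fold lower in Zab+MYC than in MYC (limma adjusted p = 1.3e-11). ADAR was 22.7-fold higher in Zab than in WT (log2 4.50 ± 0.059, limma adjusted p = 4.4e-66) and 5.84-fold lower in Zab+MYC than in Zab (limma adjusted p = 7.6e-49). It was 4.34-fold higher in Zab+MYC than in MYC (limma adjusted p = 1e-43). In MYC against WT ADAR differed by log2 -0.16 (limma adjusted p = 0.016), a call that ended with RLE scaling (adjusted p = 0.054), with edgeR (adjusted p = 0.16) and with DESeq2 (adjusted p = 0.48). It also ended without any 1 of WT replicate 2, MYC replicate 2, either Zab library or either Zab+MYC library, where log2 values ran from -0.141 to -0.072. ADAR was counted on 3 different transcripts over the 8 libraries. All WT and MYC libraries used the same one, which no Zab or Zab+MYC library used. The switch thus follows Zab, and its part in the ADAR changes with Zab was not tested.

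The FACT subunits moved little. SUPT16H, the larger subunit, at chromosome 14 from 21819636 to 21852178, stood at 89.6 ± 4.44 CPM in WT, 117 ± 1.71 in MYC, 91.4 ± 12.6 in Zab and 95.0 ± 17.1 in Zab+MYC. SSRP1, the other subunit, at chromosome 11 from 57093463 to 57103366, stood at 232 ± 40.0, 296 ± 7.47, 189 ± 6.18 and 239 ± 1.64 CPM in the same order. In MYC against WT both were called higher, SUPT16H by log2 0.37 ± 0.15 (limma adjusted p = 0.033) and SSRP1 by 0.36 ± 0.10 (limma adjusted p = 0.0022). The SUPT16H call ended with DESeq2, with library totals, and without WT replicate 1, MYC replicate 1 or MYC replicate 2 (adjusted p 0.065 to 0.17), and the SSRP1 call ended without WT replicate 2 (adjusted p = 0.18). SSRP1 was also called lower in Zab against WT (log2 -0.28, limma adjusted p = 0.036) and in Zab+MYC against MYC (-0.31, limma adjusted p = 0.027), and higher in Zab+MYC against Zab (0.34, limma adjusted p = 0.0096). Each of these 3 calls ended with DESeq2 (adjusted p = 0.28, 0.061 and 0.13) and without some single library, for the first WT replicate 1, Zab replicate 1, Zab replicate 2 or Zab+MYC replicate 2, for the second any of its 4 libraries or with library totals (adjusted p = 0.081), and for the third Zab replicate 2 or either Zab+MYC library. SUPT16H was not called in these 3 comparisons.

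**Figure D2:**
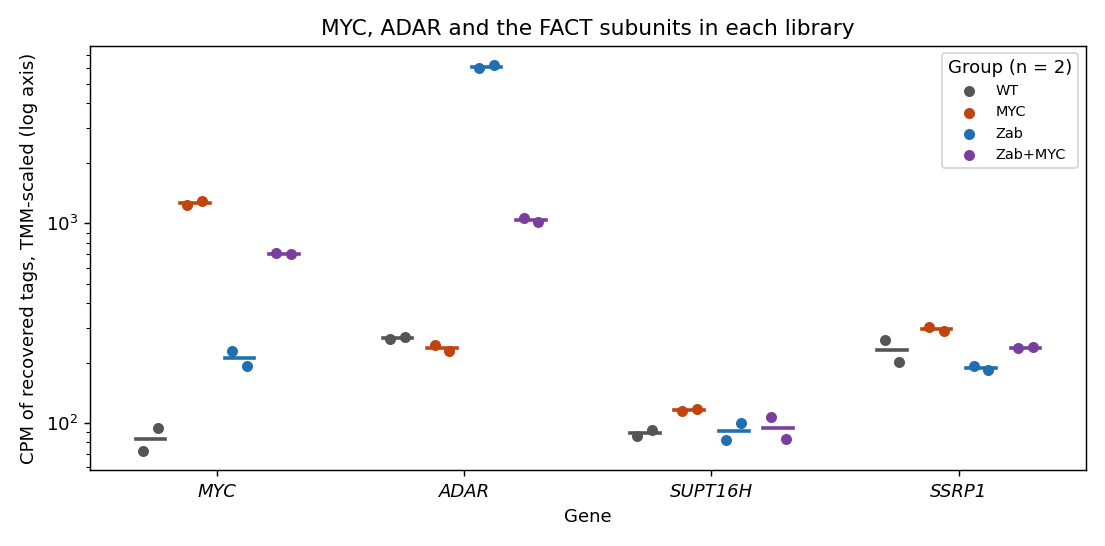
CPM of recovered tags on a log axis for MYC, ADAR, SUPT16H and SSRP1, with a point per library and a bar at the mean of 2. ADAR in Zab averages 6100 CPM against 267 in WT, and MYC in the MYC group averages 1263 CPM against 83.7 in WT.

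The first comparison, MYC against WT, asks which genes follow MYC without Zab. Genes of growth rose together, and genes of the extracellular matrix fell. Of 58 tested MYC core targets, 52 rose and 2 fell (53 and 2 adjusted over the list alone), with a median log2 of 1.70. SRM, which makes spermidine, rose 4.36-fold (log2 2.12 ± 0.043), ODC1, the rate-limiting enzyme of polyamine synthesis, rose 4.12-fold, and PA2G4, a nucleolar growth regulator, rose 3.98-fold. Of 81 ribosome biogenesis genes, 78 rose and 0 fell (79 and 0 adjusted over the list alone), median 1.61, among them RSL1D1 at 4.31-fold, EBNA1BP2 at 4.05-fold and DKC1, the pseudouridine synthase dyskerin, at 3.93-fold. The lists overlap in part, since 12 of the 60 MYC core targets belong to another list. The exon share was 76.0% in MYC and 70.9% in WT.

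Ribosomal proteins rose in 65 of 78 cases and fell in 3 (66 and 4 adjusted over the list alone), median 0.46, with RPL38 at 2.89-fold. Of 42 translation factors and tRNA synthetases, 34 rose and 2 fell (34 and 3 adjusted over the list alone), and EIF3B, an initiation factor subunit, rose 3.27-fold. Heat shock genes rose in 14 of 22 cases and fell in 2 (14 and 2 adjusted over the list alone), median 1.0, with HSPA8, a constitutive HSP70 chaperone, at 2.79-fold and FKBP4, an HSP90 co-chaperone, at 5.08-fold. Nuclear-encoded oxidative phosphorylation genes rose in 32 of 51 cases and fell in 5 (32 and 5 adjusted over the list alone), with NDUFB9 of complex I at 2.38-fold. Of 31 nucleotide synthesis genes, 17 rose and 5 fell (17 and 5 adjusted over the list alone), with NME1 at 2.92-fold and IMPDH1, of guanine nucleotide synthesis, at 4.18-fold. These lists were called by camera, with adjusted p from 7.2e-32 for MYC core targets to 0.00072 for nucleotide synthesis, and all held with an estimated correlation (adjusted p 0.0029 to 0.044).

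In the extracellular and bone matrix list 33 of 37 genes fell and 0 rose (33 and 0 adjusted over the list alone), median -1.93 (camera adjusted p = 1.4e-17, and 0.012 with an estimated correlation). COL1A1, a chain of type I collagen, fell 9.71-fold from 1140 to 116 CPM, FN1, fibronectin, fell 8.55-fold, and SPARC, osteonectin, fell 4.82-fold. Of 40 G2/M and mitosis genes, 22 fell and 4 rose (22 and 4 adjusted over the list alone), median -0.54 (camera adjusted p = 0.0027, and adjusted p = 0.13 with an estimated correlation), with TOP2A at 2.07-fold lower and FOXM1, a mitotic transcription factor, at 2.04-fold lower. Interferon-stimulated genes fell in 23 of 38 cases and rose in 3 (23 and 3 adjusted over the list alone), median -0.64 (camera adjusted p = 0.0061, and adjusted p = 0.072 with an estimated correlation), with LGALS3BP, a secreted glycoprotein, 3.19-fold lower and STAT2, an interferon signalling factor, 4.70-fold lower. Of 30 p53 targets, 14 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.034, and adjusted p = 0.13 with an estimated correlation), and the call ended without MYC replicate 2 (adjusted p = 0.05). TP53I3 fell 9.24-fold and CDKN1A, the p21 inhibitor, 1.59-fold. Of 21 immediate early genes, 11 fell and 4 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.19 with an estimated correlation), with EGR1 11.8-fold lower and SRF, the serum response factor, 2.84-fold higher. Of 8 tested replication-dependent histones, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.16 with an estimated correlation), with H1-2, a linker histone, 5.96-fold lower. KRT8, KRT17 and KRT14, keratins of epithelial cells, fell and KRT18 rose 1.32-fold, in a list where 4 of 6 fell (4 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.15 with an estimated correlation). Of 16 MYC network genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.006, and adjusted p = 0.13 with an estimated correlation), with MXD4, a MAX partner that opposes MYC, 4.55-fold lower. KRT14, at 0 tags in MYC, was at least 20.8-fold lower.

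Single genes moved further. CAMKV, a vesicle-associated kinase-like protein at chromosome 3 from 49895422 to 49907339, had 0 tags in WT and was at least 33.6-fold higher in MYC. EPHA8, an ephrin receptor, rose from 2 tags to 116.5 (ratio 48.2, 95% counting interval 11.7 to 361), and SLCO5A1, SPRR2D and ADCYAP1R1, the PACAP receptor, rose from 2, 1 and 1 tags with ratios of 29.5, 49.1 and 48.4 (intervals within 7.72 to 1790). The fitted SLCO5A1 fold was 19.3 without WT replicate 1 and 8.54 without WT replicate 2. RGS16, a regulator of G-protein signalling, rose 16.6-fold (11-fold without WT replicate 1 and 25.2-fold without WT replicate 2). IGFBP5, which binds insulin-like growth factors, at chromosome 2 from 217536828 to 217560272, fell 57.1-fold from 898 ± 4.72 to 13.9 ± 2.82 CPM. ZNF467 fell 22.2-fold, HAPLN1, a hyaluronan link protein, fell 21.1-fold, FXYD6, a sodium pump regulator, fell 20-fold and ELFN1 fell 17.8-fold. LOXL4, a lysyl oxidase of the matrix, OLFML3 and PODNL1 fell to 2, 1 and 3 tags, with ratios of 105 (counting interval 25.9 to 795), 149 (24.5 to 5570) and 59.5 (20.7 to 303). In all, limma called 5633 of 9673 genes, 2692 higher and 2941 lower, and edgeR on recovered tags called 5905. Of these, 2963 changed at least 2-fold, 1185 higher and 1778 lower. No list call was made for glycolysis, G1/S and DNA replication, MYC-repressed growth and arrest genes or hypoxia response (camera adjusted p = 0.068, 0.054, 0.054 and 0.23). With a filter of 5 CPM in 2 libraries the first 2 were called higher (adjusted p = 0.025 and 0.019) and the MYC-repressed genes lower (adjusted p = 0.042). Glycolysis was also called without WT replicate 2, MYC replicate 1, either Zab library or either Zab+MYC library (adjusted p 0.03 to 0.049), G1/S without WT replicate 2, MYC replicate 2, either Zab library or either Zab+MYC library (adjusted p 0.029 to 0.049), and the MYC-repressed genes without either Zab+MYC library (adjusted p = 0.043 and 0.042).

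The second comparison, Zab against WT, asks what Zab changes without overexpressed MYC. Interferon-stimulated genes rose strongly. In that list 27 of 38 tested members rose and 0 fell (27 and 0 adjusted over the list alone), median 1.42 (camera adjusted p = 4.7e-19, and 0.0056 with an estimated correlation). ISG15, an interferon-induced ubiquitin-like protein, at chromosome 1 from 948877 to 949919, rose 15.4-fold from 54.8 ± 1.05 to 876 ± 43.4 CPM (log2 3.95 ± 0.18). IFI6, an interferon-induced mitochondrial and ER protein, rose 17.3-fold and IFITM3, an antiviral membrane protein, rose 3.88-fold. OAS1, OAS3 and OAS2, synthetases activated by double-stranded RNA, lie next to each other on chromosome 12 from 113344767 to 113426610, and rose together.

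OAS3 rose 9.85-fold to 71.8 ± 1.97 CPM and OAS1 rose 10.3-fold from 2.52 ± 3.57 to 36.7 ± 0.843 CPM, a fold of 19.2 without WT replicate 1 and 5.49 without WT replicate 2. OAS2 and IFI27, both at 0 tags in WT, were at least 19.3-fold and 7.63-fold higher. IFI44L rose from 3 tags to 96.5 (ratio 37.9, 95% counting interval 12.2 to 181). The list of Z-nucleic acid and double-stranded RNA sensing genes rose in 5 of 10 cases and fell in 0 (5 and 0 adjusted over the list alone), median 0.87 (camera adjusted p = 3e-07, and 0.022 with an estimated correlation). Its members ADAR, OAS3, OAS1 and DDX58, the RIG-I sensor, are among them, and DDX58 rose 4.67-fold. ADAR's level may include the introduced construct, which the values do not separate from endogenous ADAR, and 4 of the other members belong to another list. Without ADAR the median was 0.61 with 4 of 9 members higher (camera adjusted p = 0.0019, and adjusted p = 0.061 with an estimated correlation), and these 4 all belong to another list.

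**Figure D3:**
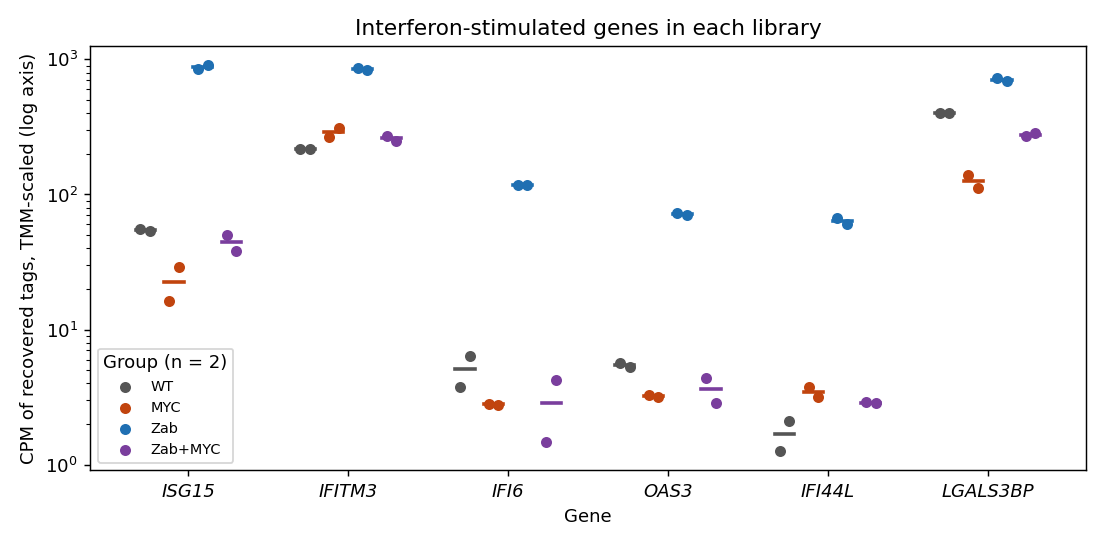
CPM of recovered tags on a log axis for 6 interferon-stimulated genes in each library, with bars at the mean of 2 libraries per group. ISG15 averages 876 CPM in Zab, 54.8 in WT, 22.7 in MYC and 44.2 in Zab+MYC.

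MYC core targets rose in 38 of 58 cases and fell in 3 (41 and 5 adjusted over the list alone), median 0.76, or 0.23 on the deposited scale, with SRM 2.46-fold and NME1, a nucleoside diphosphate kinase, 2.19-fold higher. Ribosome biogenesis genes rose in 49 of 81 cases and fell in 0 (56 and 0 adjusted over the list alone), median 0.53, or 0.01 on the deposited scale, with UTP4, a small-subunit processome component, 2.10-fold higher. Camera called both lists higher on that scale too (adjusted p = 5.1e-10 and 1e-10). Ribosomal proteins rose in 60 of 78 cases (61 adjusted over the list alone), median 0.33, but on the deposited scale their median was -0.21 and the camera direction turned (adjusted p = 0.0069). The median over all tested genes was -0.513 on that scale. The list median, and that of oxidative phosphorylation genes below, still lay above it, so the turn is not a fall in fold change against other genes. Of 42 translation factors and tRNA synthetases 24 rose (25 adjusted over the list alone), median 0.41, or -0.12 on the deposited scale, where the call was lost (adjusted p = 0.27). On the TMM scale these 4 lists held with an estimated correlation (camera adjusted p 0.0056 to 0.022). Nuclear-encoded oxidative phosphorylation genes rose in 13 of 51 cases (13 adjusted over the list alone; camera adjusted p = 0.0087, and adjusted p = 0.061 with an estimated correlation), but on the deposited scale the median of 0.11 became -0.43 and the direction turned (adjusted p = 0.0035). Of 22 heat shock genes 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.061 with an estimated correlation), and their median of 0.23 became -0.27 on the deposited scale. HSPB1, a small heat shock protein, fell 1.55-fold and HSPA8 rose 1.58-fold. Of 30 p53 targets 11 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.051 with an estimated correlation), with CDKN1A 1.88-fold higher, and the median of 0.38 became -0.13 on the deposited scale. The exon share was 60.8% in Zab and 70.9% in WT, and the deposited sum 0.705 of WT.

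Genes of mitosis fell in 27 of 40 cases and rose in 0 (31 and 0 adjusted over the list alone), median -0.64 (camera adjusted p = 1.4e-16, and 0.016 with an estimated correlation), among them FOXM1, 1.92-fold lower, and BIRC5, survivin, 1.54-fold lower. Of 37 matrix genes 20 fell and 1 rose (20 and 1 adjusted over the list alone), median -0.53 (camera adjusted p = 1.7e-09, and 0.025 with an estimated correlation), with TIMP2, a metalloproteinase inhibitor, 3.34-fold lower. Further lists that camera called lower were immediate early genes, hypoxia response, glycolysis, histones and G1/S genes, with 11, 7, 7, 2 and 8 members lower and 3, 2, 2, 0 and 1 higher (adjusted over the list alone 12, 7, 8, 2 and 8 lower). Their camera adjusted p was 0.0012, 0.0063, 0.00065, 0.024 and 0.04, and with an estimated correlation the adjusted p was 0.11, 0.07, 0.087, 0.28 and 0.1. The hypoxia and histone calls ended on the deposited scale (adjusted p = 0.11 and 0.089). The G1/S call ended without WT replicate 2, either MYC library or either Zab library (adjusted p 0.061 to 0.08). GAPDH and LDHA, glycolytic enzymes, fell 1.33-fold and 1.36-fold. MGP, matrix Gla protein, fell 8.90-fold, BHLHE41, a circadian repressor, fell 7.90-fold and STRA6, the retinol transporter, fell 7.86-fold (12.1-fold without Zab replicate 1 and 5.01-fold without Zab replicate 2). COLEC12, TEF and DRD1, the dopamine D1 receptor, fell to 1, 1 and 3 tags, with ratios of 26.5 (counting interval 4.97 to 1210), 29.4 (4.51 to 1100) and 12 (4.3 to 67.2), and IGFBP5 fell 7.30-fold. The fitted DRD1 fold was 13.7 without Zab replicate 1 and 4.35 without Zab replicate 2. In all, limma called 2363 genes, 1271 higher and 1092 lower, of which 574 changed at least 2-fold. DESeq2 called 994. On the deposited scale 5018 genes were called, 251 higher and 4767 lower.

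The third comparison, Zab+MYC against MYC, asks what Zab changes when MYC is overexpressed. In several lists that camera called higher in MYC against WT, some members were called lower, and several matrix and p53 genes were higher. MYC core targets fell in 34 of 58 cases and rose in 2 (44 and 2 adjusted over the list alone), median -0.44, with HSPD1, a mitochondrial chaperonin, 1.45-fold and NOLC1, a nucleolar phosphoprotein, 1.81-fold lower. Ribosome biogenesis genes fell in 42 of 81 cases and rose in 0 (49 and 0 adjusted over the list alone), with RSL1D1 1.55-fold and NOP58, a box C/D ribonucleoprotein, 1.61-fold lower. Ribosomal proteins fell in 44 of 78 cases and rose in 2 (53 and 3 adjusted over the list alone), and heat shock genes in 10 of 22 with 1 higher (10 and 1 adjusted over the list alone), among them HSP90AA1, 1.44-fold lower.

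Translation factors and tRNA synthetases fell in 10 of 42 cases and rose in 3 (13 and 3 adjusted over the list alone), and oxidative phosphorylation genes fell in 13 of 51 and rose in 2 (14 and 2 adjusted over the list alone). On the higher side, 13 of 30 p53 targets rose and 0 fell (20 and 0 adjusted over the list alone), median 0.46, with TP53I3 4.65-fold, XPC, a DNA damage sensor, 2.68-fold and CDKN1A 2.17-fold higher. Of 37 matrix genes 17 rose and 0 fell (17 and 0 adjusted over the list alone), median 0.44, with COL1A1 1.93-fold higher, at 225 CPM against 116 in MYC and 1140 in WT. Epithelial markers rose in 5 of 6 cases (5 adjusted over the list alone), median 0.94, or 0.89 with genes at 0 tags set to their bound, with KRT8 2.74-fold higher. These 9 lists held with an estimated correlation (camera adjusted p 0.0088 to 0.037). Interferon-stimulated genes rose in 10 of 38 cases and fell in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.04, and adjusted p = 0.11 with an estimated correlation), and their median of 0.11 became -0.04 on the deposited scale. That call also ended without Zab+MYC replicate 2 (adjusted p = 0.099). LGALS3BP was 2.21-fold higher and ISG15 1.92-fold higher, at 44.2 ± 8.38 CPM against 54.8 ± 1.05 in WT. The other called lists were histones (5 of 8 higher), cholesterol synthesis (6 of 22 higher), Z-nucleic acid and double-stranded RNA sensing (4 of 10 higher), nucleotide synthesis (6 of 31 lower, 1 higher) and histone chaperones with FACT (8 of 20 lower, 1 higher). Adjusted over the list alone the same counts were 5, 6, 4, 6 and 8. Their adjusted p with an estimated correlation was 0.11, 0.09, 0.063, 0.09 and 0.09. The sensing list was not called without ADAR, whose level may include the construct (3 of 9 higher, median 0.11, camera adjusted p = 0.18). The exon share was 69.1% in Zab+MYC and 76.0% in MYC.

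TNNT2, cardiac troponin T, at chromosome 1 from 201328142 to 201346808, rose 11.4-fold to 38.9 ± 2.07 CPM, above 10.7 ± 0.913 in WT. EDN1, endothelin 1, rose 5.47-fold and COL13A1, a transmembrane collagen, rose 5.34-fold, or 3.53-fold without MYC replicate 2. EDN2, TNFRSF14 and PDGFRB, the platelet-derived growth factor receptor beta, had 0 tags in MYC and were at least 10.7-fold, 8.26-fold and 6.98-fold higher. LOXL4 and CCBE1, a matrix protein of lymphatic growth, rose from 2 and 3 tags, with ratios of 20 (95% counting interval 4.75 to 163) and 13.1 (3.73 to 62.4). The CCBE1 call ended without MYC replicate 1 (adjusted p = 0.067). The largest falls were smaller. ZDHHC6, a palmitoyltransferase, fell 2.80-fold, DEPDC7 2.77-fold, PGF, placental growth factor, 2.55-fold, PFKFB3, which makes an activator of glycolysis, 2.50-fold, GPAM, of triglyceride synthesis, 2.50-fold, ADAMTS2, a procollagen peptidase, 2.44-fold and IL6R, the interleukin 6 receptor, 2.41-fold. PTPDC1 fell to 3 tags, with a ratio of 3.41 (counting interval 1.13 to 21.2). Each of these 8 lost its call without at least 1 of the 4 MYC and Zab+MYC libraries, with adjusted p from 0.052 to 0.53, and the fitted PTPDC1 fold was 1.47 without Zab+MYC replicate 1 and 4.59 without Zab+MYC replicate 2. DESeq2 gave no adjusted p for these 8 or for the rises named here other than LOXL4. In all, limma called 1933 genes, 1146 higher and 787 lower, and 480 rose and 31 fell at least 2-fold. The split depends on the scale, with 1335 higher and 570 lower by library totals and 575 higher and 2947 lower on the deposited scale. edgeR called 2415 genes, 46.1% of them higher, and DESeq2 887, 41.0% higher. The count fell to 1178 without MYC replicate 1, 1208 without MYC replicate 2 and 1136 without Zab+MYC replicate 2.

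The fourth comparison, Zab+MYC against Zab, asks what overexpressed MYC changes when Zab is present. Interferon-stimulated genes fell strongly. In that list 33 of 38 fell and 0 rose (35 and 0 adjusted over the list alone), median -1.78 (camera adjusted p = 4.3e-32, and 0.0019 with an estimated correlation). ISG15 fell 19.1-fold to 44.2 ± 8.38 CPM (log2 -4.26 ± 0.18), IFI6 fell 25.8-fold, OAS3 fell 13.3-fold and IFITM3 fell 3.24-fold to 260 CPM, with 217 in WT and 290 in MYC. OAS2 fell to 0 tags and was at least 19.2-fold lower. OAS1, to 2 tags, had a ratio of 25.9 (95% counting interval 8.47 to 271), and IFIT3, an interferon-induced protein with tetratricopeptide repeats, to 1 tag, a ratio of 50.2 (7.14 to 1720). The fitted OAS1 fold was 7.96 without Zab+MYC replicate 1 and 19.2 without Zab+MYC replicate 2.

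IFI44L fell 13.5-fold and IFIT1 fell 17.5-fold to 3.90 ± 5.51 CPM. The IFIT1 fold was 7.85 without Zab+MYC replicate 1 and 38.3 without Zab+MYC replicate 2, and DESeq2 did not call it (adjusted p = 0.051). Sensing genes fell in 5 of 10 cases and rose in 0 (5 lower and 1 higher adjusted over the list alone), among them ADAR and EIF2AK2, the RNA-activated kinase PKR, 2.76-fold lower (camera adjusted p = 1.3e-05, and 0.028 with an estimated correlation). Without ADAR 4 of 9 fell (camera adjusted p = 0.0081, and adjusted p = 0.093 with an estimated correlation), and these 4 all belong to another list. MYC core targets rose in 42 of 58 cases and fell in 0 (46 and 0 adjusted over the list alone), median 0.61, with ODC1 2.27-fold and LDHA, lactate dehydrogenase A, 1.84-fold higher. Ribosome biogenesis genes rose in 53 of 81 cases and fell in 0 (60 and 0 adjusted over the list alone), with DDX21, a nucleolar helicase, 1.93-fold higher. Glycolysis genes rose in 13 of 21 cases and fell in 3 (13 and 3 adjusted over the list alone), with ENO1, enolase, 1.39-fold higher, and G1/S genes in 14 of 43 with 0 lower (14 and 0 adjusted over the list alone), with CCND1, cyclin D1, 1.77-fold higher. Heat shock, oxidative phosphorylation, nucleotide synthesis and translation genes rose in 12 of 22, 22 of 51, 12 of 31 and 15 of 42 cases (13, 25, 15 and 15 adjusted over the list alone). Matrix genes fell in 26 of 37 cases and rose in 1 (27 and 1 adjusted over the list alone), median -0.73, with COL5A1 and COL3A1, fibrillar collagens, 8.29-fold and 9.12-fold lower. These lists held with an estimated correlation (camera adjusted p 0.0019 to 0.038). Of 78 ribosomal proteins 13 rose and 21 fell (15 and 21 adjusted over the list alone) with no list call (camera adjusted p = 0.13), and their median of -0.008 became 0.149 on the deposited scale, where the list was called higher (adjusted p = 3.5e-05). The median over all tested genes was 0.141 on that scale, close to that of the list.

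Lists whose call was lost with an estimated correlation were G2/M (16 of 40 higher, 1 lower; adjusted p = 0.095), the MYC network (7 of 16 higher, 1 lower; adjusted p = 0.13), cholesterol synthesis (8 of 22 higher; adjusted p = 0.095), histone chaperones with FACT (6 of 20 higher; adjusted p = 0.093) and p53 targets (6 of 30 lower; adjusted p = 0.095). Adjusted over the list alone these counts were 18, 8, 8, 7 and 5. BIRC5 was 1.71-fold higher and GDF15, a stress cytokine, 2.85-fold lower. CAMKV, EPHA8 and SPRR2D rose from 1, 2 and 1 tags, with ratios of 54.2, 18.9 and 31 (95% counting intervals within 4.41 to 2000), and CCBE1 rose from 3 tags with a ratio of 7.61 (2.42 to 40.5). GABRA5, a GABA receptor subunit, rose 7.81-fold to 39.7 ± 5.96 CPM, DNAAF3, a dynein assembly factor, rose 4.84-fold and KLHL21, a ubiquitin ligase adaptor, rose 4.78-fold. In all, limma called 2592 genes, 1385 higher and 1207 lower, and 696 changed at least 2-fold. DESeq2 called 1070, and 1712 were called without Zab+MYC replicate 2. On the deposited scale 2159 were higher and 783 lower. The exon share was 69.1% in Zab+MYC and 60.8% in Zab.

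**Figure D4:**
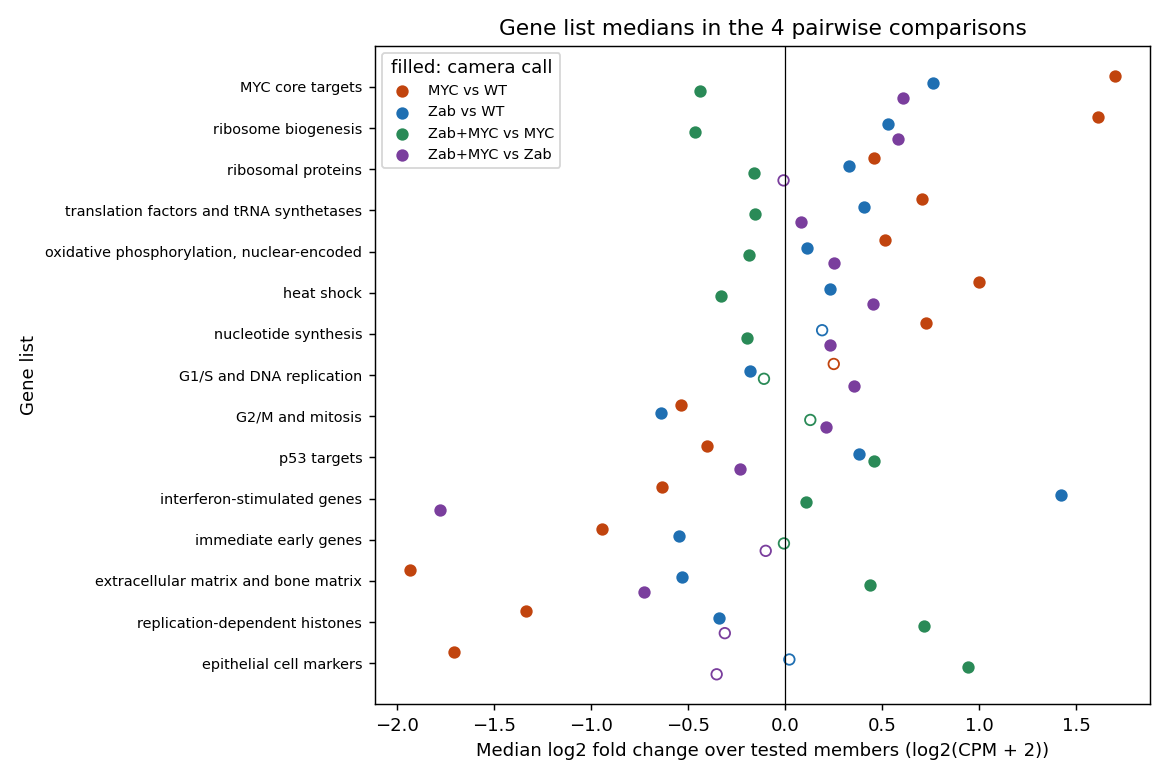
Median log2 fold change over the tested members of 15 gene lists in the 4 comparisons, with filled points where camera made a call. The interferon-stimulated list lies at 1.42 in Zab against WT and at -1.78 in Zab+MYC against Zab, and at 0.91 and -1.62 in these on the deposited scale.

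The interaction asks whether the MYC effect differed with Zab present. Most MYC core targets and ribosome biogenesis genes had a lower MYC effect with Zab than without it, and most matrix genes a less negative one. Of 58 MYC core targets 43 had a lower MYC effect with Zab and 5 a higher one (46 and 5 adjusted over the list alone), with SRM at log2 2.12 ± 0.043 without Zab and 0.37 ± 0.043 with it. Ribosome biogenesis genes had a lower MYC effect in 62 of 81 cases and ribosomal proteins in 67 of 78 (64 and 67 adjusted over the list alone). Matrix genes had a higher, that is less negative, MYC effect in 21 of 37 cases (23 adjusted over the list alone), with FN1 at a difference of log2 2.37 ± 0.19. Interferon-stimulated genes had a lower MYC effect in 16 of 38 cases and a higher one in 1 (20 and 3 adjusted over the list alone), with IFITM3 at -2.11 ± 0.12. G2/M genes had a higher MYC effect in 26 of 40 cases (28 adjusted over the list alone), with FOXM1 at 1.37 ± 0.15. Camera adjusted p for these lists ran from 6.2e-53 for ribosomal proteins to 4.6e-07 for interferon-stimulated genes, and with an estimated correlation from 0.0039 to 0.019. In all, limma called 2695 genes, 1408 higher and 1287 lower, edgeR 2753 and DESeq2 1304, and on the deposited scale 2061 were higher and 829 lower.

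Over the 5633 genes called in MYC against WT, the MYC effect with Zab had a slope of 0.368 on the effect without it (Pearson r 0.763, Spearman rho 0.783, across genes, which are not independent replicates), and 85.3% had the same sign. Slopes through 0 were 0.400 for genes MYC raised and 0.347 for those it lowered, and over the genes called with Zab present the slope was 0.540. Over 4 combinations of single replicates the slope ran from 0.350 to 0.360. Both comparisons called 1122 genes higher and 953 lower, against 385.4 and 367 for independent lists, and 75 in opposite directions against 757. Without Zab+MYC replicate 2, 619 were lower in both, against 223.1. COL1A1 fell in both, 9.71-fold without Zab and 3.53-fold with it. For the 2363 genes called in Zab against WT, the Zab effect with MYC had a slope of -0.115 on the effect without MYC (r -0.210, rho -0.250), and 36.1% had the same sign. This slope depends on the genes taken, with -0.343 over the genes called in Zab+MYC against MYC, and slopes through 0 of -0.0158 for genes Zab raised and -0.200 for those it lowered. The former was -0.0533 with RLE scaling, -0.0342 with a filter of 5 CPM in 2 libraries, -0.0563 without Zab replicate 1, -0.00921 without WT replicate 2, and -0.0377 to -0.0243 without MYC replicate 2, Zab replicate 2 or either Zab+MYC library. The latter was -0.128 without Zab replicate 1. Both called 130 higher and 74 lower, against 150.6 and 88.85 for independent lists, and 561 in opposite directions against 232.8. Without Zab+MYC replicate 2 the same counts were 81, 51 and 384, against 74.84, 53.94 and 127.2, and without MYC replicate 1 they were 89, 47 and 368, against 83.29, 51.74 and 132.4.

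MYC against WT and Zab against WT share the WT libraries. Their log2 fold changes over all 9673 genes had a correlation of 0.553, with 0.531 in simulated unchanged groups, and a covariance of 0.327 with 0.0357 simulated. Both called 915 genes higher and 769 lower, against 353.7 and 332 for independent lists. SRM, PA2G4 and IGFBP5 moved the same way in both. MYC against WT and Zab+MYC against MYC share the MYC libraries, with opposite sign, and had a covariance of -0.388 with -0.0239 simulated (r -0.725, simulated -0.402). In these, 697 genes were higher then lower and 1015 lower then higher, against 219 and 348.4. Zab against WT and Zab+MYC against Zab share the Zab libraries and had a covariance of -0.0213 with -0.0402 simulated (r -0.0656, simulated -0.531). There 349 genes were higher and 193 lower in both, against 182 and 136.3, while 215 were higher then lower and 193 lower then higher, against 158.6 and 156.4. With 1 library of the shared group given to each comparison, the covariance was 0.295 and 0.288 in the first pair, -0.355 and -0.358 in the second, and 0.018 and 0.0245 in the third, where its sign turned, over both ways to split. Each side then rests on 1 library, so part of the excess in the counts of genes may come from shared libraries.

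**Figure D5:**
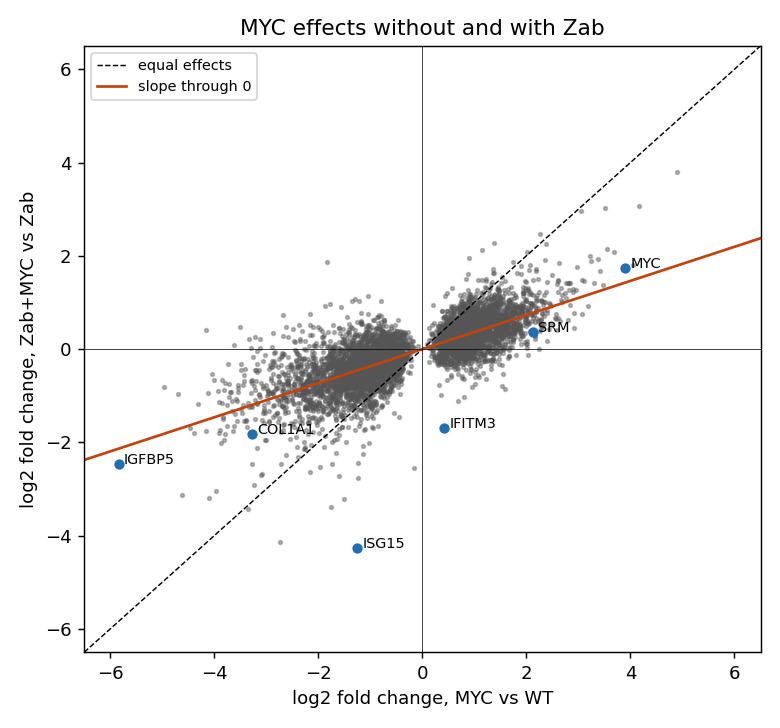
Log2 fold change of MYC against WT (horizontal) and of Zab+MYC against Zab (vertical) for the 5633 genes called in MYC against WT, 1 point per gene. The dashed line marks equal effects and the solid line the slope through 0 of 0.366, with MYC, SRM, IFITM3, ISG15, COL1A1 and IGFBP5 named.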

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

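The tests of the MYC core target level, of a mixture of cells and of the Zab level, and the sensing list without ADAR, were chosen only after the result was seen. The results given here stand out because the MYC effect differed between cells with and without Zab, by the interaction in limma, which called 2695 genes, 1408 with a higher and 1287 with a lower MYC effect with Zab. MYC itself had an interaction of log2 -2.16 and ADAR of -2.38. The genes with the largest positive values were PDGFRB at 4.56, LOXL4 at 4.15, EDN2 at 3.99, OLFML3 at 3.73, CCNG2, a cyclin G, at 3.70 and TNNT2 at 3.69. The genes with the largest negative values were OAS2 at -4.41, IFI44L at -4.33, IFI6 at -4.15, OAS1 at -3.29, OAS3 at -3.21 and ISG15 at -3.01. For PDGFRB, EDN2 and OAS2, at 0 tags in at least 1 group, and for LOXL4, OLFML3, CCNG2, OAS1 and IFI44L, at 1 to 3 tags in at least 1 group, these fitted values depend on the pseudocount and are no bounds. Leaving out 1 library moved OAS1 between -2.39 (without WT replicate 2) and -4.19 (without WT replicate 1), and OLFML3 between 3.06 and 4.38 (without Zab replicate 1 or 2).

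Gene lists differed in the same way. Median interaction values were -1.01 for MYC core targets, -1.0 for ribosome biogenesis, -0.54 for ribosomal proteins, -0.58 for translation factors, -0.56 for heat shock, -0.28 for oxidative phosphorylation and -1.05 for interferon-stimulated genes, and 0.66 for G2/M and 0.92 for matrix genes, all called by camera also with an estimated correlation. The median was -0.43 for nucleotide synthesis (adjusted p = 0.073 with an estimated correlation) and -0.97 for Z-nucleic acid and double-stranded RNA sensing (adjusted p = 0.073 with an estimated correlation), which was not called without ADAR (camera adjusted p = 0.19). The MYC network lay at -0.31 (adjusted p = 0.21 with an estimated correlation), and its call also ended on the deposited scale and without WT replicate 2, Zab replicate 2 or Zab+MYC replicate 2 (adjusted p 0.051 to 0.075). Immediate early genes lay at 0.98 (adjusted p = 0.14 with an estimated correlation), histones at 1.04 (adjusted p = 0.14 with an estimated correlation) and epithelial markers at 1.30 (adjusted p = 0.051 with an estimated correlation).

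The MYC effect was smaller with Zab present, with a slope of 0.368 over the genes called in MYC against WT, and of 0.540 over those called in Zab+MYC against Zab, beside a ratio of 0.445 between MYC's own log2 differences with and without Zab. Picking genes by chance extremes of single libraries is argued against. Genes picked in replicate 1 of MYC and WT showed a slope of 0.878 (95% interval 0.867 to 0.890, 3116 genes) in replicate 2. Chance extremes that both libraries of a group share, as from 1 culture, would pass this test, so it cannot speak against them. The lower MYC transcript level in Zab+MYC than in MYC may account for it, since 144 of the 1933 genes called in Zab+MYC against MYC, 7.45% (6.32 to 8.71), lay outside their WT to MYC range with calls against both, a share between the bounds of 5% and 10% set before the test, so that it cannot be told apart from other causes. For MYC core targets the median of Zab+MYC against WT was 1.276, while 1.337 would follow from the MYC levels, and the difference of -0.061 exceeds 2 standard errors of the paired differences (0.022) but not of the median itself (0.074), whereas those of matrix genes (0.373), p53 targets (0.458) and cholesterol synthesis (0.317) exceed 2 of either error. The first form of that test used only the smaller error and spoke against the explanation, and the second error was added after that outcome was seen, and all these values assume effects in proportion to log2 MYC, so it is left open, as is an effect of Zab itself.

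Interferon-stimulated genes were high in Zab and not in Zab+MYC. Another transcript picked per symbol is argued against, since the 18 members with the same transcript in all libraries had a median of -1.367 (-1.862 to -0.925) in Zab+MYC against Zab, an interval that lies below the -0.3 the explanation needs but reaches above the bound of -1 set before the test. MYC and ADAR together argue against a mixture of Zab and MYC cells only. They give shares of Zab cells of 53% and 13.7%, 39.3 points apart. The list members alone do not argue against it. Their log2 ratio of observed to mixed level had a median of -0.498 (-1.084 to -0.326), just short of the bound of -0.5. A mixture that also holds cells with neither factor was not tested, and the differing shares do not speak against it. A lower level of the Zab construct, with ADAR as its stand-in, stays open. The values do not separate the construct from endogenous ADAR, whose own level may have changed too. This limits the test here and the share from ADAR above. ADAR kept 13.8% of its excess and the list members a median of 2.06% (0.0594 to 5.91), which argues against a fall in proportion to ADAR. The list need not follow ADAR in proportion, and the test could count against the explanation only if ADAR were not lower in Zab+MYC than in Zab. That ADAR was lower was known before the test was chosen, so this cannot be told apart. An effect of MYC on these genes stays open, with a list median of -0.64 in MYC against WT (camera adjusted p = 0.0061, and adjusted p = 0.072 with an estimated correlation).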

How the results depend on the processing

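The edgeR test, the pseudocounts of 1 and 5 CPM, the deposited scale, gene lists without ADAR, the covariance of MYC and Zab effects under settings other than the main one, and the restriction to genes with 1 transcript were chosen only after the data were seen. With genes restricted to those with the same transcript in all libraries, 4604 genes were tested and 2831, 1360, 1044 and 1447 were called in MYC against WT, Zab against WT, Zab+MYC against MYC and Zab+MYC against Zab, with 1496 for the interaction, fewer because fewer genes were tested. With an added 2-fold threshold the counts were 2963, 574, 511, 696 and 1415 in the same order. DESeq2 called 994, 887 and 1070 in the last 3 pairwise comparisons and 1304 for the interaction, and the cause was not tested. On the deposited scale 5018 genes were called in Zab against WT and 3522 in Zab+MYC against MYC, because that scale shifts all genes by 1 factor per library. With an estimated correlation camera called 8, 8 and 9 lists in the first 3 comparisons and 9 for the interaction, against 15, 16, 15 and 15 at the preset correlation, and 11 against 16 in Zab+MYC against Zab, and the cause was not tested. A higher correlation is not the cause for every list. In MYC against WT the lost lists of p53 targets and interferon-stimulated genes had estimated correlations of -0.03 and -0.0061, below the preset 0.01. The other lists lost there, G2/M, the MYC network, immediate early genes, histones and epithelial markers, lay above it. Interferon-stimulated genes in Zab+MYC against Zab kept their call, at an estimated correlation of -0.0061. Yet their camera adjusted p went from 4.3e-32 to 0.0019. The 2 settings thus differ in more than the correlation, and a call lost between them need not reflect correlated genes. On the deposited scale the camera direction turned for ribosomal proteins (adjusted p = 0.0069), oxidative phosphorylation (adjusted p = 0.0035) and heat shock (adjusted p = 0.62) in Zab against WT and for ribosomal proteins in Zab+MYC against Zab (adjusted p = 3.5e-05), turns that follow from the same shift. In Zab against WT these list medians (-0.212, -0.427 and -0.265) still lay above the median of -0.513 over all tested genes on that scale. In Zab+MYC against Zab the ribosomal protein median was 0.149, beside 0.141 over all tested genes. With each comparison given its own WT library the covariance of MYC and Zab effects was 0.292 in place of 0.327, as the mean of both ways to split. Without ADAR the sensing list lost its call in Zab+MYC against MYC (adjusted p = 0.18) and for the interaction (adjusted p = 0.19). A filter of 5 CPM in 2 libraries added list calls for nucleotide synthesis in Zab against WT (adjusted p = 0.043), glycolysis and G1/S in Zab+MYC against MYC (adjusted p = 0.048 and 0.034) and MYC-repressed genes in Zab+MYC against Zab (adjusted p = 0.043). The deposited scale added 1, 4 and 2 list calls in the last 3 pairwise comparisons, the last being ribosomal proteins higher and MYC-repressed genes lower (adjusted p = 0.041), and 1 for the interaction. The slope of MYC effects was 0.354 with a filter of 5 CPM in 2 libraries, and the cause was not tested.

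With each library left out in turn, a lone library is assumed to vary like the other groups. Calls then ranged from 4796 to 5980 in MYC against WT, 1665 to 2343 in Zab against WT, 1136 to 2213 in Zab+MYC against MYC, 1712 to 2648 in Zab+MYC against Zab and 2129 to 2500 for the interaction. Zab+MYC against MYC gave 1178 without MYC replicate 1, 1208 without MYC replicate 2 and 1136 without Zab+MYC replicate 2, and Zab+MYC against Zab gave 1712 without Zab+MYC replicate 2. Lists called ranged from 15 to 18, 15 to 17, 14 to 16, 16 to 17 and 14 to 15. The slope of MYC effects ranged from 0.348 to 0.367, that of Zab effects from -0.115 to -0.0876, and the covariance of MYC and Zab effects from 0.331 to 0.376. With all 8 libraries these were 0.3679, -0.1154 and 0.327, at or outside the ends of these ranges. The low-count filter was run anew in each fit, so 9952 to 10397 genes were tested in place of 9673. The changed gene set cannot be told apart from the library left out. Of 4515 values of named genes under RLE scaling, library totals, DESeq2, the block or a library left out, 4426 stayed on their side of the threshold, 89 lost their call and 0 turned direction. DESeq2 gave no adjusted p for 43 of the 380 named results, which are not in this tally. With edgeR 0 of 373 called values had the opposite sign and 3 were not called, among them ADAR in MYC against WT. Most named genes were picked in these same data for large changes or small p. Few losses were thus likely from the start, and these tallies say nothing about genes at large. On the deposited scale small positive values in Zab against WT turned sign, as its shift of -0.516 for all genes fixes, which says nothing about single genes. Filters and pseudocounts were not run on named genes. DESeq2 moved the fold of some low genes by over 1.5 times, among them, as log2, ZNF467 (-5.49) and FXYD6 (-4.96) in MYC against WT and GABRA5 (3.89), IFI6 (-5.34), IFI44L (-4.47), OAS3 (-4.38) and COL3A1 (-3.81) in Zab+MYC against Zab. RLE scaling, library totals, edgeR, thinning, no filter, the pseudocounts and the 4 libraries alone left every total count of called genes within 1.5 times, though genes called lower in Zab+MYC against MYC went from 787 to 1301 with edgeR, beside 1114 higher, so that the majority turned. Other majorities turned too. In Zab against WT, 1271 higher and 1092 lower became 1133 and 1247 by library totals, 1150 and 1169 with edgeR, and 1119 and 1157 with the 4 libraries alone. In Zab+MYC against Zab, 1385 higher and 1207 lower became 1255 and 1330 by library totals.

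Replicate numbers did not pair the libraries, with correlations of deviations from -0.0226 to 0.0143. With the replicate number as a block, 5650, 2434, 2010, 2657 and 2756 genes were called. The block ended the G1/S call in Zab against WT (adjusted p = 0.083), made one for nucleotide synthesis there (adjusted p = 0.048) and changed no other list call. A fit on several entries per symbol was not run, because each symbol had 1 entry, and the 4 libraries alone were not run for the interaction, which needs all 8. Depth limits low genes, since at 686992 to 1326170 exon tags per library many genes hold few tags.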

Other observations

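The test of Zab+MYC against WT and the values on list medians expected from MYC levels, olfactory receptors, detection and odd steps were chosen only after the data were seen. In Zab against WT 7 of 20 hypoxia genes fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.07 with an estimated correlation), a call that ended on the deposited scale (adjusted p = 0.11). CA12, a carbonic anhydrase, was 3.65-fold lower (log2 -1.87 ± 0.18 SE), DDIT4, an mTOR inhibitor, 2.79-fold lower (-1.48 ± 0.24) and BNIP3L, a mitophagy receptor, 2.62-fold lower (-1.39 ± 0.24). IER3, an immediate early gene, stood at 365 CPM in WT, 84.9 in MYC, 109 in Zab and 115 in Zab+MYC, while FOSL1, an AP-1 subunit, was 2.27-fold higher in Zab than in WT (log2 1.19 ± 0.15). FDFT1, squalene synthase, was 2.20-fold higher in Zab+MYC than in MYC, at 171 ± 3.74 CPM against 77.6 ± 18.6 (SD, n = 2).

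FACT and histone chaperones were called lower in Zab+MYC against MYC (camera adjusted p = 0.015, and adjusted p = 0.09 with an estimated correlation) and higher in Zab+MYC against Zab (camera adjusted p = 0.014, and adjusted p = 0.093 with an estimated correlation), and not called in MYC against WT or Zab against WT. They had 8 of 20 members higher and 3 lower in MYC against WT (8 and 3 adjusted over the list alone, camera adjusted p = 0.1), a call made with a filter of 5 CPM in 2 libraries (adjusted p = 0.042). In Zab against WT 2 were higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.24), and on the deposited scale the list was called lower (adjusted p = 0.00093). Its median was -0.053 on the TMM scale. On the deposited scale it was -0.588, beside -0.513 over all tested genes, so that call is not read as a fall against other genes. Topoisomerases and R-loop resolution genes and genes of RNA polymerase II pausing and elongation were called by camera in none of the 5 contrasts, with adjusted p from 0.47 to 0.80 and from 0.30 to 0.83. NF-kappaB targets and amino acid and unfolded protein response genes were not called in any of them either, with adjusted p from 0.27 to 0.98 and from 0.23 to 0.80. Marker genes of blood cells summed to 26.3 CPM in WT, 48.7 in MYC, 32.6 in Zab and 44.0 in Zab+MYC, and those of neural cells to 499, 354, 388 and 367. These lists had 2 and 4 members with enough tags to test, and the sums were not tested.

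MYC core targets lay in the order of MYC levels over the groups. Against WT their medians were 0.76 in Zab, 1.28 in Zab+MYC and 1.70 in MYC, beside MYC log2 values of 1.33, 3.06 and 3.90. If list medians followed log2 MYC in proportion from WT to MYC, matrix genes would lie at -1.519 in Zab+MYC against WT and lay at -1.146, p53 targets at -0.315 and lay at 0.142, and epithelial markers at -1.342 and lay at -0.265. The differences were 0.373, 0.458 and 1.077, with standard errors of 0.17, 0.099 and 0.28 for paired differences and 0.13, 0.12 and 0.86 for the median. For matrix and p53 genes, and for cholesterol synthesis at 0.317 (0.084 and 0.11), the difference exceeded 2 of either error, but proportion is an assumption, so this excludes nothing. Against WT, Zab+MYC had 4088 called genes, 2092 higher and 1996 lower.

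Genes rose at least 2-fold far more often than they fell in Zab+MYC against MYC, 480 against 31. Background reads are argued against, since 3927 genes with 0 tags in WT and Zab rose by 0.0657 CPM per kb of exon, 1.57% (1.38 to 1.84) of the median rise of 4.2 CPM per kb in the 480 genes. Another transcript picked per symbol is argued against as well, since 94% (90 to 96.8) of such changes were rises among 217 changes in genes with 1 transcript. Genes lowered in MYC and less so in Zab+MYC may account for the pattern, since 438 of the 480, 91.2% (88.4 to 93.6), were called lower in MYC against WT, against 30.4% of all genes tested. Both comparisons use the MYC libraries, so chance lows there could add to this share.

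Over 402 olfactory receptor genes the WT libraries held 15.5 and 16.5 tags, MYC 14.5 and 17, Zab 20 and 23.5, and Zab+MYC 26.5 and 22. As summed CPM by library total this ran from 12.8 in MYC replicate 2 to 30.9 in Zab+MYC replicate 2. Thinned to the smallest library, 13585 and 13754 genes were detected in WT, 13000 and 13030 in MYC, 13425 and 13631 in Zab and 14217 and 13982 in Zab+MYC. Among values of 1 or 2 steps, odd steps made up 35.5% and 33.6% in the Zab+MYC libraries and 23.2% to 26.3% in the others. A difference between groups in these values was not tested.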
